A study of Mus musculus with 8 samples.

How the data were processed

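RNA sequencing libraries of 8 mice were analysed, 4 from mice given tacrolimus and 4 from mice given vehicle, 1 library per mouse. The groups and replicate numbers were taken from the sample titles. Per the labels' protocols, the RNA came from CD8+ lymphocytes sorted by flow cytometry out of digested subcutaneous tumors and was extracted with Trizol. Per the submitters' processing notes, the tools named are HISAT2 2.1.0, RSEM 1.3.1 and DESeq2 1.24.0, with the mouse genome build GRCm38.p6; the notes give no role or order for them.

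The deposited files hold 1 value per gene for 55487 Ensembl genes in each library, printed to 2 decimals, and no header or label names their unit. The unit was inferred from the values to be FPKM (fragments per kilobase of transcript, scaled to library size), so the deposited FPKM values were already scaled for gene length and library size by the authors. The values of a library summed to between 890182 and 926808. Low values of genes with a single annotated transcript of 500 to 1500 bases fell at steps that shrank with transcript length. After multiplication by the transcript length less 240 or 260 bases, between 84.7% and 86.5% of these low values lay within 0.15 steps of a whole multiple of the step of their library, against 30.0% for evenly spread values. The step corresponds to an estimated 15748000 to 19047600 fragments per library, so the depth was similar between libraries, with tacrolimus replicate 3 the deepest. Fragment counts were not recovered for most genes, and no count model was used.

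The design, the gene lists and the rule for naming genes were fixed before the data were examined. The design assumed counts and named the test to be used for normalized values, and that test was used. Values were transformed to log2(FPKM + 1). Genes with an FPKM of 1 or more in at least 4 libraries were kept, which left 13032 genes. They were compared with limma 3.58.1 (lmFit, then eBayes with a mean-variance trend) in R 4.3.3, with treatment as the only term and Benjamini-Hochberg adjustment over the genes tested, at an adjusted p under 0.05. Fold changes are tacrolimus minus vehicle on the log2(FPKM + 1) scale, which understates the change of genes with low values. Group levels are given as mean FPKM ± SD.

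Of the 27 gene lists written from textbook knowledge, 26 had at least 5 tested members. Each was compared with the other genes tested by camera of limma with a preset correlation of 0.01, two-sided, with adjustment over the 26 lists. Camera with an estimated correlation and fry, which asks whether the genes of a list move one way on balance, were alternatives. The level of a list in a mouse was its mean log2(FPKM + 1) over the tested members. Levels were compared with an exact two-sided permutation test over the 70 assignments of 4 mice to each group, for which the smallest possible p is 0.0286. Permutation p values given with a covariate come from another test, over all 40320 orders of residuals, and can lie below 0.0286. They are exact only in that every order was used. Residuals of a fit are not strictly interchangeable, so these p values are approximate. The B cell and plasma cell list had too few tested members in the main comparison.

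The rule for naming genes took the genes past the adjusted threshold with the largest changes or, where fewer than 5 passed in a direction, the 5 with the smallest unadjusted p and a mean log2 value of 1 or more. It added up to 4 members of each list with the smallest unadjusted p and a fixed set of T cell, calcineurin, melanoma and myeloid genes. Some genes that the rule takes are left out of the text. Predicted gene models, pseudogenes and receptor variable segments stayed out of the first part. Among genes with an unadjusted p under 0.05, 89 such models were higher and 90 lower in the tacrolimus libraries. Symbols were matched by Ensembl identifier, and 346 identifiers had none. Coordinates are those of the GENCODE M21 annotation of GRCm38.

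The limma and camera steps were tested on simulated data with the means and SDs of this comparison. With 12796 genes in the step, 51 of 100 genes changed by 1 on the log2 scale and 90 of 100 changed by 2 were recovered. In the same run, 14 of 12549 unchanged genes were called as well. With no change, no gene and no list was called. Genes were simulated independently of each other, so this run does not test how often camera calls lists of correlated genes. No library duplicated another: at most 0.266% of the values at a mean FPKM of 1 or more were identical in a pair of libraries.

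Alternatives were other pseudocounts, other filters on low values, other scalings, robust variance estimation, library weights, covariates for the level of melanoma, macrophage or T cell genes, removal of gene classes, the replicate number as a block, and each library left out in turn. Python 3.11.15 and matplotlib 3.10.9 were used for the depth estimate and the plots.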

Results

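The series asks how intermittent tacrolimus affects T cells that infiltrate a tumor. Tacrolimus (FK506) binds the immunophilin FKBP12 and inhibits calcineurin, the phosphatase that activates NFAT transcription factors downstream of the T cell receptor. C57BL/6 mice carried subcutaneous tumors of B16F10, a pigmented mouse melanoma line. Treatment began 7 to 9 days after injection of the tumor cells, at a tumor volume of about 50 mm3. Mice received tacrolimus at 3 mg/kg, or vehicle, every 5 days. Tumors were taken 6 days after the first dose. RNA of the cells sorted as CD8+ tumor-infiltrating lymphocytes was sequenced from 4 tacrolimus and 4 vehicle mice. The deposited FPKM values correspond to an estimated 15748000 to 19047600 fragments per library. Between 12724 and 13628 genes per library had an FPKM of 1 or more.

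Transcripts of melanoma cells were far more abundant in every library than those of T cells. Pmel, a melanosome structural protein, was at 4956 ± 736 FPKM in the tacrolimus group and 6477 ± 1629 in the vehicle group (SD, n = 4 each). Tyrp1, a melanin synthesis enzyme, was at 1667 ± 278 and 2255 ± 476 FPKM. Cd8a, the alpha chain of the CD8 co-receptor, was at 18.6 ± 12.2 FPKM in the tacrolimus group and 71.7 ± 54.5 in the vehicle group (mean 44.6 without vehicle replicate 1). Cd3e, a chain of the T cell receptor complex, was at 22.5 ± 16.7 and 80.8 ± 45.6 FPKM (tacrolimus mean 14.6 without replicate 1). By rank within a library, Pmel stood between place 7 and place 21 of all genes, and Cd8a between place 841 and place 9931. The macrophage gene Lyz2, which encodes lysozyme, was at 167 ± 52.7 and 444 ± 315 FPKM. Cd4 was at 0.18 ± 0.13 and 0.99 ± 0.62 FPKM and was not tested, because too few libraries reached the minimum.

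**Figure D1:**
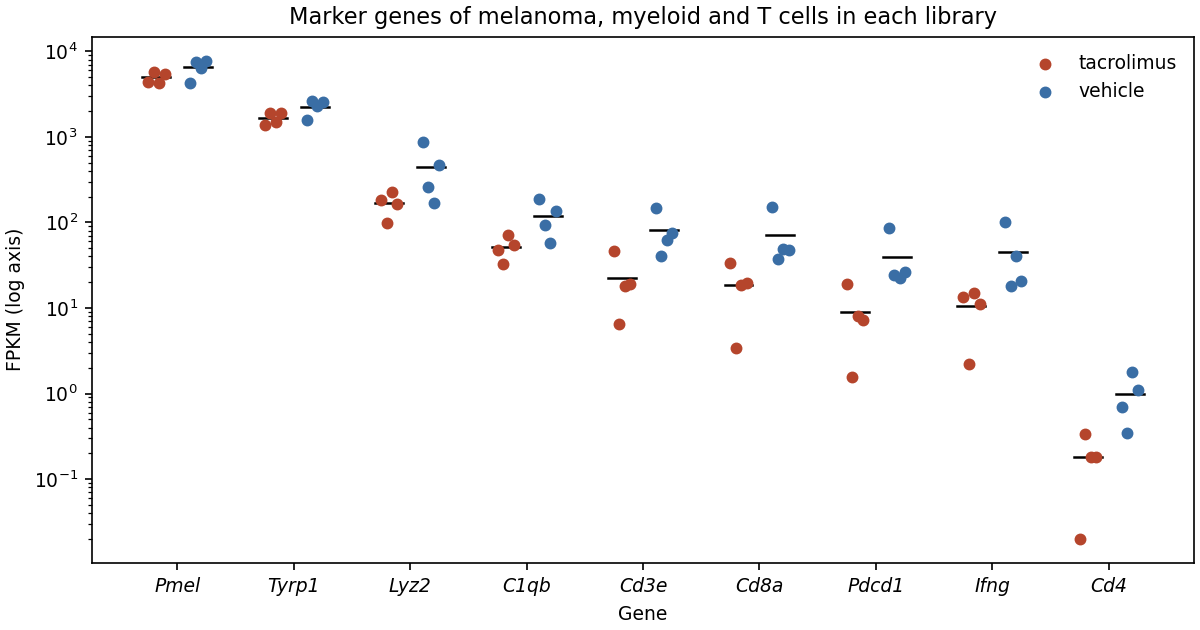
FPKM (log axis) of 9 marker genes in each of the 4 tacrolimus and 4 vehicle libraries, with points for libraries and lines for group means. Pmel lies between 4223 and 7772 FPKM, while Cd8a lies between 3.40 and 153 FPKM.

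Vehicle replicate 1 stood apart from the other libraries. It took 63.9% of the sum of squares of the first principal component, which held 33.5% of the variance over the genes tested. Its Cd8a level of 153 FPKM and Lyz2 level of 876 FPKM were the highest of the 8 libraries. Tacrolimus replicate 2 had the lowest Cd8a level, at 3.40 FPKM. Spearman correlations between libraries ran from 0.862 to 0.958 across genes, which are not independent replicates.

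The main comparison asked which genes differed between tacrolimus and vehicle mice. No gene passed an adjusted p of 0.05 in limma, and the smallest adjusted p was 0.139. At an unadjusted p under 0.05, 208 genes were higher and 2056 lower in the tacrolimus libraries, where chance gives 652 in all. This split depended on the scaling. The median gene lay at -0.19 (log2) in the values as deposited and at 0.01 after median-of-ratios scaling, under which 746 genes were higher and 725 lower at an unadjusted p under 0.05. With an upper-quartile scaling 746 were higher and 690 lower. With the level of melanoma markers as a covariate, 455 genes passed an adjusted p of 0.05 in limma, of which 438 were lower. The groups did not overlap for 1434 genes, or 11.0% of those tested, where chance gives 2.86%. The chance figures of 652 genes and 2.86% are averages, and genes that move together can spread single splits widely around them. Another split of the 8 libraries gave 2187 genes at an unadjusted p under 0.05.

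The genes with the smallest unadjusted p among those lower in the tacrolimus group are given as values, since none passed the adjustment. Ifi47, an interferon-inducible GTPase (ENSMUSG00000078920; GRCm38 chromosome 11, 49076587 to 49096974), was at 9.59 ± 1.18 FPKM with tacrolimus and 24.7 ± 5.60 with vehicle, a log2 difference of -1.26 (SE 0.18, limma adjusted p = 0.139). Igtp, a GTPase of the same family (chromosome 11, 58199556 to 58207591), was at 5.65 ± 1.04 and 15.1 ± 2.68 FPKM. Sh3bp1 (chromosome 15, 78899768 to 78912051) was at 6.70 ± 1.16 and 15.6 ± 1.39 FPKM. Ptpn6, the haematopoietic phosphatase SHP-1 (chromosome 6, 124720707 to 124738714), was at 48.5 ± 2.13 FPKM with vehicle, with a log2 difference of -0.77 (SE 0.12). Limd2 (chromosome 11, 106156256 to 106160860) was at 26.2 ± 3.85 and 59.0 ± 13.5 FPKM. On the higher side, 4 of the 5 genes are given. Npas3 (chromosome 12, 53248677 to 54072175) was at 53.3 ± 11.9 FPKM with tacrolimus and 29.8 ± 3.01 with vehicle. Klhl29 (chromosome 12, 5077472 to 5375682) was at 5.19 ± 4.61 and 0.45 ± 0.19 FPKM (tacrolimus mean 2.90 without replicate 4). Purg (chromosome 8, 33386325 to 33417467) was at 3.20 ± 0.86 and 0.61 ± 0.39 FPKM. Agrp (chromosome 8, 105566698 to 105637393) was at 0.54 ± 0.37 FPKM with vehicle, with a log2 difference of 1.41 (SE 0.28). In each of the genes named here the groups did not overlap, which follows largely from their choice by the smallest unadjusted p in these same values.

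Of the 26 gene lists, 18 were called by camera, 13 lower and 5 higher, and 1 of them held with an estimated correlation. In the values as deposited 75.7% of all genes tested were lower, and members of a list can move together. Counts of lower or passing members are therefore not independent support. Genes of T cell identity fell as a group in the tacrolimus libraries. All 20 members had a lower mean, with a mean log2 difference of -1.71, or 3.26-fold (camera adjusted p = 1.52e-08 in limma). The call was lost with an estimated correlation (adjusted p = 0.446; 1.50e-17 to 0.446 over the alternatives). No member passed over all genes tested, and 17 passed adjusted over the list alone. Cd247, the zeta chain of the receptor complex, was at 4.79 ± 3.35 FPKM with tacrolimus and 19.9 ± 12.3 with vehicle. Lcp2, an adaptor of receptor signaling, was at 3.12 ± 1.43 and 13.1 ± 8.07 FPKM, and Trac, the constant segment of the receptor alpha chain, at 20.9 ± 15.2 and 82.7 ± 46.5 FPKM. The list level per mouse was 3.38 ± 0.96 with tacrolimus and 5.09 ± 0.98 with vehicle (log2, SD, n = 4; exact permutation p = 0.0286, adjusted p = 0.0571). The groups did not overlap in the values as deposited. Under each of the 3 other scalings the groups overlapped, and with upper-quartile scaling the difference was -1.47 (exact permutation p = 0.0571). Macrophage and monocyte markers were also lower on average in the tacrolimus group, though their levels overlapped between the groups. With their level as a covariate the T cell identity difference was -0.65 (SE 0.71, exact permutation p = 0.391) and the call was lost.

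Lists of T cell function fell alongside. Activation genes induced through the T cell receptor fell by 1.02 on average on the log2 scale (adjusted p = 3.44e-07 by camera and 0.440 with an estimated correlation), and all 22 members had a lower mean, 16 of them passing adjusted over the list alone. Nr4a1, an orphan nuclear receptor induced by receptor signaling, was at 50.2 ± 9.34 FPKM with tacrolimus and 88.1 ± 15.7 with vehicle. Egr1 was at 12.6 ± 3.30 and 29.4 ± 11.5 FPKM, and the costimulatory receptor Icos at 2.97 ± 1.83 and 14.9 ± 11.1 FPKM. Tacrolimus replicate 2, with the lowest Cd8a level, had 53.9 FPKM of Nr4a1 and 13.9 of Egr1. Replicate 1 had 55.6 and 13.8, so Nr4a1 and Egr1 did not follow the T cell level there. Icos did, at 0.68 FPKM in replicate 2 and 4.82 in replicate 1. Cytokines and chemokines of activated T cells fell by 1.31 (adjusted p = 6.60e-06 by camera and 0.446 with an estimated correlation), and 10 of 15 members passed adjusted over the list alone. Xcl1, a chemokine that attracts cross-presenting dendritic cells, was at 8.47 ± 3.46 and 40.7 ± 23.4 FPKM. Ltb was at 7.23 ± 3.81 and 26.7 ± 19.4 FPKM. Ifng, which encodes interferon gamma, was at 10.4 ± 5.68 and 44.6 ± 38.1 FPKM, and Tnf at 5.53 ± 0.79 and 16.6 ± 18.1 FPKM. Vehicle replicate 1 raised the vehicle mean of several genes. Its Tnf level was 43.5 FPKM, where the other vehicle libraries lay between 4.56 and 9.60, and its Ifng level 99.8 FPKM, where they lay between 18.1 and 40.0. Without it the vehicle means were 7.59 FPKM for Tnf, 26.3 for Ifng, 17.4 for Ltb and 9.48 for Icos. Il2 was at 0.08 ± 0.11 and 0.14 ± 0.18 FPKM, below the minimum for testing, and its direction turned without vehicle replicate 1 (vehicle mean 0.05), while tacrolimus replicate 3 carried the tacrolimus mean (0.02 without it). Once the T cell identity level was a covariate, the activation difference was -0.25 (SE 0.23, exact permutation p = 0.318) and the cytokine difference -0.20 (SE 0.30, exact permutation p = 0.532). Both calls were lost, and both were lost with the macrophage level as a covariate.

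Inhibitory receptors and exhaustion genes fell by 1.09 on average (adjusted p = 4.20e-06 by camera and 0.446 with an estimated correlation), with 5 of 25 members passing adjusted over the list alone. Pdcd1, which encodes PD-1, was at 8.92 ± 7.25 FPKM with tacrolimus and 39.8 ± 31.0 with vehicle. Ctla4 was at 11.2 ± 7.59 and 65.0 ± 71.8 FPKM, Tox at 3.23 ± 2.65 and 9.73 ± 6.79 FPKM, and Lag3 at 0.56 ± 0.75 and 2.05 ± 1.28 FPKM. Havcr2, which encodes TIM-3, was at 152 ± 24.0 and 184 ± 30.6 FPKM. It was at 170 FPKM in tacrolimus replicate 2, with the lowest Cd8a level, and at 141 in vehicle replicate 1, with the highest. Havcr2 thus did not follow Cd8a, and which cells it came from was not tested. With the T cell identity level as a covariate the exhaustion difference was -0.04 (SE 0.16, exact permutation p = 0.798), the call was lost and the list no longer ranked below the other genes. The call was also lost with the macrophage covariate. Cytotoxic effector genes fell by 0.89 (adjusted p = 0.00429 by camera and 0.600 with an estimated correlation), and their levels per mouse overlapped (exact permutation p = 0.171, adjusted p = 0.248). None of the 26 members passed adjusted over the list alone, and the call was lost without vehicle replicate 1 (mean -0.49, camera adjusted p = 0.412; 1.83e-09 to 0.876 over the alternatives) and without tacrolimus replicate 2. Prf1, which encodes perforin, was at 6.98 ± 5.78 and 24.5 ± 12.8 FPKM, Gzmb, a granzyme, at 37.9 ± 27.2 and 104 ± 108 FPKM, and Ctsw at 10.8 ± 7.25 and 40.0 ± 27.3 FPKM. Vehicle replicate 1 had 264 FPKM of Gzmb, where the other vehicle libraries had 37.3 to 71.5. Without it the vehicle means were 50.1 FPKM for Gzmb, 29.1 for Ctla4, 24.4 for Pdcd1, 26.5 for Ctsw and 6.47 for Tox. Tacrolimus replicate 1 in turn raised the tacrolimus mean, which without it was 5.59 FPKM for Pdcd1, 1.92 for Tox and 0.20 for Lag3. Its Prf1 level was 15.3 FPKM, where the other tacrolimus libraries lay between 1.99 and 5.34. The cytotoxic difference turned to 0.45 with the T cell covariate, and camera called the list higher (adjusted p = 6.81e-08). The levels per mouse did not pass (SE 0.13, permutation p = 0.0132 over the residual orders, adjusted p = 0.142).

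Naive, memory and progenitor genes fell by 0.77 on average (adjusted p = 0.00181 by camera and 0.446 with an estimated correlation), with 11 of 25 members passing adjusted over the list alone. Tcf7, a transcription factor of naive and progenitor T cells, was at 4.77 ± 1.34 FPKM with tacrolimus and 11.7 ± 1.35 with vehicle. Klf2 was at 30.6 ± 7.23 and 64.1 ± 13.9 FPKM. Among the tacrolimus libraries both genes were highest in replicate 2 (6.33 FPKM of Tcf7 and 39.1 of Klf2), which had the lowest Cd8a level. Their levels are thus not those of T cells alone. The call was lost without vehicle replicate 1 (mean -0.50, camera adjusted p = 0.212; 4.77e-06 to 0.979 over the alternatives). Tissue residency and homing genes fell by 1.06 (adjusted p = 2.71e-04 by camera and 0.446 with an estimated correlation), with 10 of 20 members passing adjusted over the list alone. The chemokine receptor Ccr8 was at 0.84 ± 0.50 and 7.19 ± 4.58 FPKM. Some members of these lists are shared between them. The differences with the T cell covariate were -0.19 for the naive and memory list and -0.11 for the residency list, and both calls were lost, as with the macrophage covariate.

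Interferon response genes fell in the tacrolimus libraries. In the list of interferon gamma response and antigen presentation genes, all 30 members had a lower mean, 28 passed adjusted over the list alone, and the mean log2 difference was -1.06, or 2.09-fold (adjusted p = 3.62e-16 by camera and 0.440 with an estimated correlation). Of the named members, Iigp1, an immunity-related GTPase, was at 4.27 ± 1.04 FPKM with vehicle, with a log2 difference of -1.22. Tapbp, the tapasin of the peptide-loading complex, was at 18.2 ± 3.77 and 40.7 ± 10.9 FPKM. The level per mouse was 3.52 ± 0.18 with tacrolimus and 4.59 ± 0.47 with vehicle, without overlap (exact permutation p = 0.0286, adjusted p = 0.0571). Type I interferon response genes fell by 0.73 (adjusted p = 1.52e-08 by camera and 0.440 with an estimated correlation), with all 33 members lower and 15 passing adjusted over the list alone. Irf9, a transcription factor of the type I pathway, was at 6.05 ± 0.66 and 11.9 ± 0.71 FPKM, and Zbp1 at 3.12 ± 0.64 and 15.3 ± 11.7 FPKM (vehicle mean 9.47 without replicate 1). T cell and macrophage genes were also lower on average in the tacrolimus group. Macrophage levels overlapped, with vehicle replicate 3 at 4.12 and tacrolimus replicate 3 at 4.43. The type I call was lost with the T cell covariate (-0.31, SE 0.17, exact permutation p = 0.141) and with the macrophage covariate (-0.34, SE 0.14, exact permutation p = 0.0609). Camera called the interferon gamma list with both, but its differences of -0.52 and -0.72 had permutation p values much like that of the type I list with the macrophage covariate (SE 0.19 and 0.28, exact permutation p = 0.0660 and 0.0618, adjusted p = 0.275 and 0.309).

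**Figure D2:**
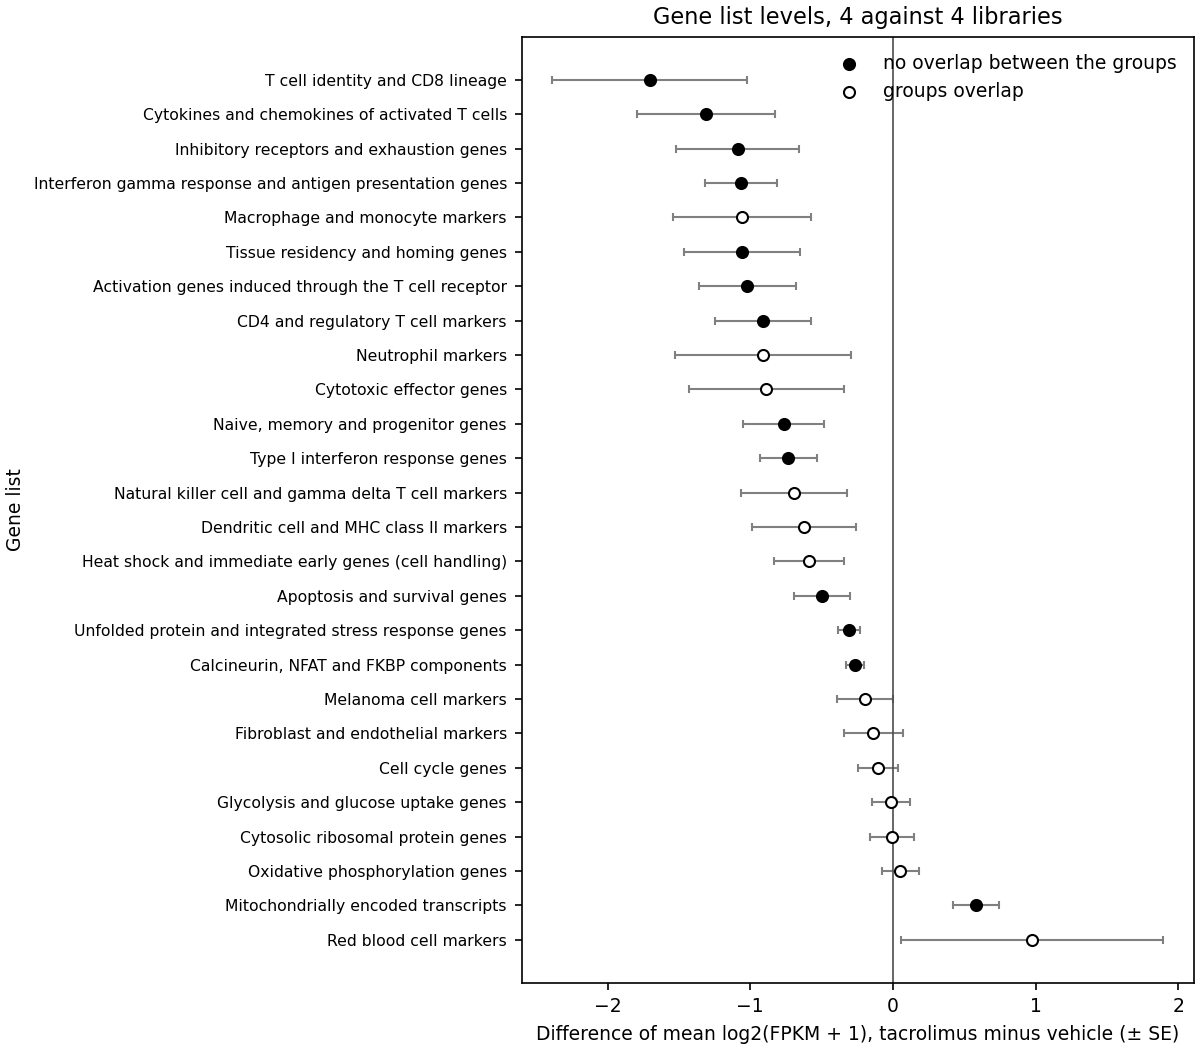
Difference of the list level, the mean log2(FPKM + 1) over the tested members, tacrolimus minus vehicle, for 26 gene lists with its SE (n = 4 libraries each). Filled points are lists whose groups do not overlap, 12 of them lower and 1 higher in the tacrolimus libraries, without correction for the shift of the median gene of -0.19.

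Markers of other cell types did not move alike. Macrophage and monocyte markers fell by 1.06 on average (adjusted p = 9.05e-07 by camera and 0.446 with an estimated correlation), with 9 of 24 members passing adjusted over the list alone, and their levels overlapped between the groups (exact permutation p = 0.0857). Their difference with the T cell covariate was -0.20 (SE 0.54, exact permutation p = 0.690) and the call was lost. Csf1r, the receptor of a macrophage growth factor, was at 2.50 ± 0.41 FPKM with tacrolimus and 8.70 ± 4.99 with vehicle, and the complement gene C1qb at 51.6 ± 16.1 and 118 ± 56.0 FPKM. Melanoma cell markers were not called (mean -0.19, camera adjusted p = 0.994), and neither were dendritic cell and MHC class II markers (mean -0.62, adjusted p = 0.0659), neutrophil markers (mean -0.91, adjusted p = 0.196), CD4 and regulatory T cell markers (mean -0.91, adjusted p = 0.196), natural killer and gamma delta T cell markers (mean -0.69, adjusted p = 0.312) or fibroblast and endothelial markers (mean -0.14, adjusted p = 0.270). Melanoma markers were called lower without vehicle replicate 1 (mean -0.35, camera adjusted p = 0.0421; 0.00104 to 0.998 over the alternatives) and with the T cell covariate (-0.59, exact permutation p = 0.0317, adjusted p = 0.198) or the macrophage covariate (-0.43, exact permutation p = 0.146). Without vehicle replicate 1 the means were -0.29 for dendritic cell, -0.35 for neutrophil and -0.41 for natural killer markers. Several of these lists were called in alternatives. Dendritic cell markers were called lower without vehicle replicate 2 or 4 or tacrolimus replicate 3, under median-of-ratios and upper-quartile scaling, with no filter on low values, with library weights and with the melanoma covariate, and higher with the T cell covariate (difference 0.07, exact permutation p = 0.851). Neutrophil markers were called lower without vehicle replicate 2, under the same scalings, with no filter and with the melanoma covariate. CD4 and regulatory T cell markers were called lower with upper-quartile scaling, no filter, the melanoma covariate and fry (adjusted p = 0.0430). Natural killer markers were called lower without vehicle replicate 2 and with the melanoma covariate, and fibroblast markers higher without vehicle replicate 2. The fibroblast mean was then 0.02, and it was -0.03 without tacrolimus replicate 2. In these lists, S100a9 was at 14.8 ± 6.01 and 62.2 ± 71.2 FPKM, Tnfrsf4 at 7.35 ± 6.20 and 35.5 ± 27.9 FPKM, Fcer1g at 68.5 ± 25.4 and 174 ± 117 FPKM, and Lum at 2.75 ± 0.47 and 4.57 ± 1.32 FPKM. The vehicle mean without replicate 1 was 26.8 FPKM for S100a9, 21.7 for Tnfrsf4 and 119 for Fcer1g, and the tacrolimus mean of Tnfrsf4 without replicate 1 was 4.63 FPKM. Red blood cell markers were higher (mean 0.98, adjusted p = 1.60e-04 by camera and 0.440 with an estimated correlation), but the levels overlapped (exact permutation p = 0.371) and the mean difference was 0.22 without vehicle replicate 2. Hbb-bs, a beta globin, was at 1656 ± 1016 and 965 ± 886 FPKM (vehicle mean 634 without replicate 4). The B cell and plasma cell list had 3 tested members and was not tested in the main comparison. With no filter on low values it had 18 members and was called lower (mean -0.45, camera adjusted p = 7.98e-04).

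**Figure D3:**
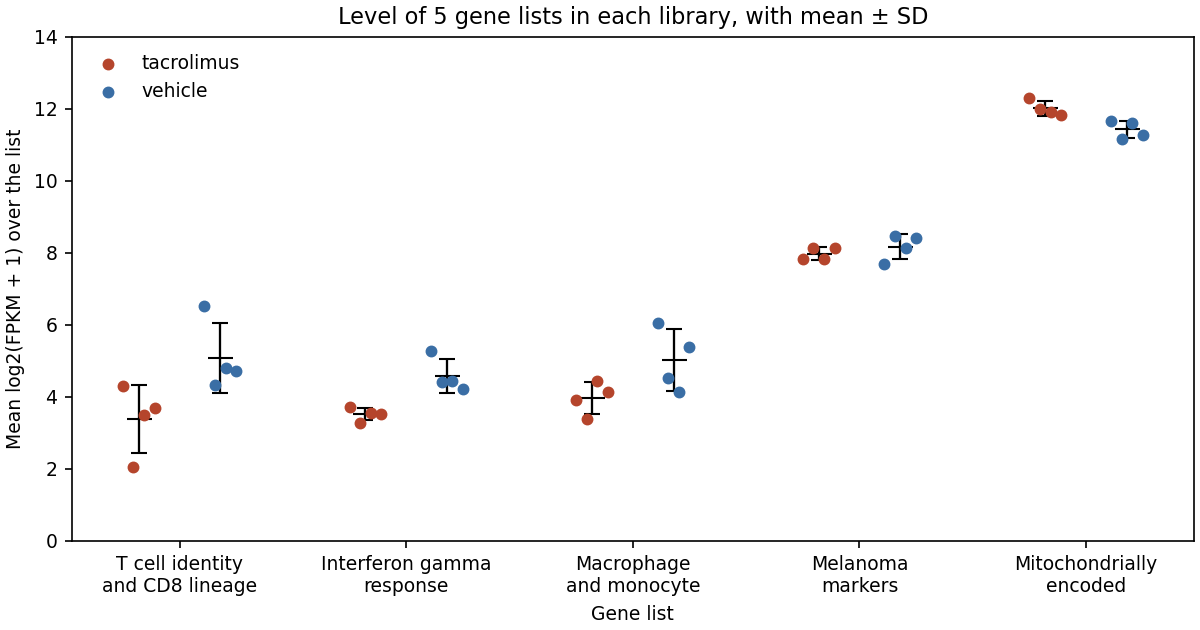
Mean log2(FPKM + 1) of 5 gene lists in each library, with the mean and SD of each group (n = 4). The interferon gamma list lies between 3.29 and 3.72 in the tacrolimus libraries and between 4.22 and 5.27 in the vehicle libraries, while the melanoma markers overlap.

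Mitochondrially encoded transcripts rose in the tacrolimus libraries. All 14 members had a higher mean, with a mean log2 difference of 0.58 (adjusted p = 3.62e-16 by camera), and 8 passed adjusted over the list alone. It was the single list whose call held with an estimated correlation (adjusted p = 0.0209; 2.53e-18 to 0.0228 over the alternatives). The ATP synthase subunit mt-Atp6 was at 13320 ± 755 FPKM with tacrolimus and 9160 ± 1148 with vehicle, and mt-Nd2, a complex I subunit, at 3335 ± 624 and 2148 ± 295 FPKM. These transcripts share sequence with nuclear copies, so their levels are uncertain one by one. Nuclear genes of oxidative phosphorylation, glycolysis and the cytosolic ribosome ranked above the other genes tested, while their own means lay near 0. The mean differences were 0.05 for oxidative phosphorylation (adjusted p = 6.55e-07 by camera and 0.534 with an estimated correlation), -0.01 for glycolysis (0.00336 and 0.548) and -0.01 for ribosomal proteins (4.66e-04 and 0.612). With each library left out in turn, the sign turned, from -0.02 to 0.14 for oxidative phosphorylation and from -0.08 to 0.07 for glycolysis. The glycolysis call was lost without vehicle replicate 1 or 4, and the ribosomal call without vehicle replicate 4 or tacrolimus replicate 3. With the T cell or the macrophage covariate the oxidative phosphorylation and glycolysis calls were lost. For glycolysis and ribosomal proteins the median was 0.01, opposite in sign to the mean. The levels of these 3 lists overlapped between the groups, and no member passed adjusted over the list alone. By mean, 35 of 50 oxidative phosphorylation, 17 of 30 glycolysis and 29 of 53 ribosomal members were higher. The members given here, chosen by smallest unadjusted p, were lower. Sdha was at 111 ± 13.8 and 141 ± 14.9 FPKM, and the glucose transporter Slc2a3 at 4.28 ± 0.66 and 8.76 ± 4.01 FPKM.

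Genes of the calcineurin pathway are not specific to T cells, and melanoma transcripts dominated every library, so the levels below are not those of T cells alone. Fkbp1a, which encodes FKBP12 (chromosome 2, 151542483 to 151561692), was at 315 ± 30.8 FPKM with tacrolimus and 356 ± 63.3 with vehicle. Ppp3ca, a catalytic subunit of calcineurin, was at 15.1 ± 2.31 and 16.9 ± 7.75 FPKM, Nfatc2 at 14.6 ± 3.74 and 16.6 ± 1.52 FPKM, and Rcan1, a calcineurin-responsive inhibitor, at 12.6 ± 0.89 and 16.5 ± 4.56 FPKM. The differences of Fkbp1a, Ppp3ca and Nfatc2 changed sign under median-of-ratios and upper-quartile scaling. Nfatc1, an NFAT gene that is itself induced by receptor signaling, was at 2.84 ± 1.68 and 8.55 ± 4.34 FPKM, and the calcium channel gene Orai1 at 10.7 ± 1.91 and 18.5 ± 2.62 FPKM. The list of calcineurin, NFAT and FKBP components was not called (mean -0.27, camera adjusted p = 0.196), but it was called lower by fry (adjusted p = 0.0362) and by camera with no filter on low values (adjusted p = 0.00926; 0.00926 to 0.915 over the alternatives), and 1 of its 23 members passed adjusted over the list alone. Its levels of 4.88 ± 0.09 and 5.15 ± 0.08 per mouse did not overlap (exact permutation p = 0.0286, adjusted p = 0.0571). Neither fry nor the permutation test compares the list with other genes, and the median gene itself lay at -0.19 in the values as deposited. Much of the list difference may be that shift.

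Stress and survival genes fell as well. Unfolded protein and integrated stress response genes fell by 0.31 on average (adjusted p = 0.00179 by camera and 0.446 with an estimated correlation), with 10 of 35 members passing adjusted over the list alone. For comparison, the median gene lay at -0.19. Xbp1 was at 55.0 ± 6.75 FPKM with tacrolimus and 86.0 ± 9.14 with vehicle, and the chaperone Hspa5 at 305 ± 48.3 and 437 ± 40.9 FPKM. Heat shock and immediate early genes, which respond to cell handling, fell by 0.59 (adjusted p = 2.86e-04 by camera and 0.446 with an estimated correlation), with 5 of 23 members passing adjusted over the list alone and a mean of -0.37 without vehicle replicate 1. Their levels overlapped (exact permutation p = 0.0571, adjusted p = 0.106). Fosb was at 9.53 ± 2.03 and 22.4 ± 5.62 FPKM. Apoptosis and survival genes fell by 0.50 (adjusted p = 0.0241 by camera and 0.446 with an estimated correlation), with no member passing adjusted over the list alone, and the call was lost without vehicle replicate 1 (mean -0.32, camera adjusted p = 0.288; 4.45e-04 to 0.705 over the alternatives) and without tacrolimus replicate 2. The heat shock and apoptosis calls were lost with the T cell or the macrophage covariate. Mcl1 was at 49.1 ± 6.12 and 80.7 ± 27.0 FPKM, and Fas at 1.22 ± 0.46 and 4.88 ± 4.50 FPKM (vehicle mean 2.63 without replicate 1). Cell cycle genes were not called (mean -0.10, adjusted p = 0.270), except without vehicle replicate 2 (mean -0.01), under median-of-ratios and upper-quartile scaling and with the melanoma covariate, with Mki67 at 8.50 ± 2.15 and 5.81 ± 2.62 FPKM and Mcm4 at 26.5 ± 4.74 and 40.8 ± 3.30 FPKM. For cell cycle genes, fibroblast markers and melanoma markers, camera placed the list above the other genes tested although its mean lay below 0.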

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

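The tests of single libraries, of T cell share and of splits at the adjusted p or under other scalings, and the scalings used as tests, were chosen after the result or the data were seen. In 202 groups of 4 libraries examined, 10 had a library far from the other 3, where chance gives about 10.1, so the flags do not exceed chance in number. In the tacrolimus group the gap took a share of 0.836 of the range for Ifng, where replicate 2 lay at 2.21 FPKM and the others between 11.2 and 14.8. The share was 0.834 for Havcr2 (replicate 4 at 117 FPKM against 160 to 170), 0.928 for Nr4a1 (replicate 3 at 36.3 against 53.9 to 55.6) and 0.886 for Egr1 (replicate 3 at 7.68 against 13.8 to 14.9). In the vehicle group it was 0.833 for the cytokine and chemokine list, in which replicate 1 lay at 5.70 and the others between 3.88 and 4.19. Replicate 1 was also apart for Pdcd1 (0.876; 86.2 FPKM against 22.3 to 26.4), Ctla4 (0.938; 173 against 27.0 to 30.3), Cd160 (0.836; 19.1 against 4.18 to 5.47) and Slc2a3 (0.879; 14.8 against 6.31 to 7.02). The remaining flag was Mki67 (0.831; replicate 4 at 9.71 against 4.27 to 4.94).

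T cell genes were lower in the tacrolimus libraries. Leaving out any single library left the T cell identity difference at -1.23 or below, which argues against a single library as its cause. It does not cover 2 libraries together. Vehicle replicate 1 lay at a list level of 6.52, where the other vehicle libraries lay between 4.32 and 4.80. Tacrolimus replicate 2 lay at 2.04, where the other tacrolimus libraries lay between 3.50 and 4.29. Both widen the difference, so its size depends on them. Under the other scalings the difference nearest to 0 was -1.47, with an SE of 0.69, while the median gene moved from -0.19 to 0.01 under median-of-ratios scaling. The difference thus stayed well below 0. The exact permutation p was 0.0571 under all 3 scalings, because the groups overlapped, and this missed the bound set beforehand. A part played by scaling is therefore not settled. Camera called the list under all 3 scalings (largest adjusted p = 1.46e-08). It compares the list with the other genes, which a scaling moves alike, so its call could not test scaling. That look at camera was added after the result was seen. All 20 members were lower and their estimated correlation within groups was 0.91, as a lower share of T cells in the tacrolimus libraries may give. Neither value tests that share. Members that move together fall together whatever the cause, and a correlation within groups does not bear on the difference between them. Macrophage markers were lower too (mean -1.06), but with the T cell level as a covariate their difference was -0.20 (SE 0.54, exact permutation p = 0.690), so the values do not separate the T cell and macrophage levels. Melanoma transcripts dominate every library, so the libraries may hold RNA of unsorted tumor or of many tumor cells in the sort. Neither was tested, and a treatment effect stays open as untested.

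Interferon response genes were lower by 1.06 (log2) in the interferon gamma list. With the T cell identity level as a covariate the difference was -0.52 (SE 0.19), with an exact permutation p of 0.0660 over the residual orders. With the macrophage level as a covariate it was -0.72 (SE 0.28, exact permutation p = 0.0618). Fewer T cells or macrophages in the libraries therefore cannot be told apart from a lower interferon response, because both differences lay between the bounds set beforehand. A lower supply of interferon gamma by fewer T cells may link both patterns and was not tested.

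Mitochondrial transcripts were higher in the tacrolimus libraries. Summed with the 4 abundant nuclear copies, the protein-coding genes were still higher by 0.53 (log2), without overlap (exact permutation p = 0.0286), which argues against reads shifting between the genes and their copies. Under the other scalings the list difference nearest to 0 was 0.59, with an exact permutation p of 0.0286. Of the lists that bear on cell handling and survival, heat shock genes were at -0.59 and apoptosis genes at -0.50. Mitochondrial ribosomal RNA took 7.04 ± 4.13% of the summed FPKM with tacrolimus and 4.51 ± 2.65% with vehicle (SD, n = 4). Tacrolimus replicate 1 held 13.1%. The other tacrolimus libraries lay between 4.14% and 5.99%, within the vehicle range of 1.94% to 8.17%. None of these measures RNA integrity or counts dying cells, and both stay open as untested.

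The counts were compared with those of all 35 splits of the 8 libraries into groups of 4. For genes past an adjusted p of 0.05 the real count was 0 in limma and the highest other was 3. A count of 0 is matched by all 35 splits whatever the data, so this comparison says nothing about chance. For genes past an unadjusted p of 0.05, the real count of 2264 was reached in 1 split, the real one. The highest other in the values as deposited was 2187, a narrow margin that does not exclude chance. Under median-of-ratios scaling 1 split reached the real 1471 (highest other 1256). Under upper-quartile scaling 2 splits reached the real 1436 (highest other 1516), and with the same total per library 2 reached the real 2272 (highest other 2316). The real split was therefore not the highest under these last 2 scalings, and chance is not excluded there either. For gene lists called by camera, 13 of the 35 splits called as many as the real 18, and the highest other called 21, so chance is not excluded for the number of lists. Under median-of-ratios and upper-quartile scaling the real split called 21 and 22 lists and no other split as many, while the highest others called 20 and 21. With the same total per library 14 of 35 splits called as many.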

How the results depend on the processing

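The planned edgeR fits (TMM and its other normalizations, library size and count filters), DESeq2 and limma-voom with or without quality weights were not run, because the values are not counts. Alternatives added after seeing the data are the scalings, the filter at 5, library weights, robust variance, the T cell covariate, a pseudocount of 0.5 for list levels, splits under other scalings and leaving out vehicle replicate 1 with tacrolimus replicate 2. The cause of the differences below was not tested.

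No gene was called with pseudocounts 0.1 or 0.5, without a filter, at an adjusted p under 0.1 or under any scaling. With the melanoma covariate 455 genes passed in limma, and 1 passed without vehicle replicate 1 (range 0 to 1 with each library left out). With the replicate number as a block, 121 genes passed, of which 115 were lower, and 18 lists were called. Correlations of same-numbered deviations were 0.21, 0.28, -0.02 and -0.02. Replicates 1 and 2 correlated best with their own number, and replicates 3 and 4 did not. So few correlations do not settle whether the numbers pair the mice.

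At an unadjusted p under 0.05, 426 genes were higher with no filter, 746 with median-of-ratios and upper-quartile scaling, 332 with the T cell covariate and 313 without vehicle replicate 1 and tacrolimus replicate 2. With each library left out, 134 to 285 were higher and 1308 to 2465 lower. Under the 2 scalings 725 and 690 were lower.

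Of 18 lists called, 1 (the mitochondrial list, higher) was called with an estimated correlation, with 0 lower. Fry called 9, with 8 lower and 1 higher. With the macrophage covariate 6 lists were called (3 lower, 3 higher), 5 of them among the 18 and melanoma newly lower. The T cell covariate gave 8 calls (3 lower), 5 of them among the 18, with melanoma newly lower, dendritic cell newly higher and cytotoxic turned to higher. These covariates each ended 12 of the 18 calls. With the melanoma covariate 22 lists were called, 17 of them among the 18, with ribosomal proteins lost and cell cycle, dendritic, neutrophil, CD4 and natural killer newly called. The list that made a covariate was not tested with it. With gene classes removed 16 lists were tested and 14 called, all among the 18. Without a filter 21 were called, with calcineurin, dendritic, neutrophil, B cell and CD4 lists new. Called higher were 3 lists with no filter, 2 with gene classes removed and 3 to 7 with each library left out. List levels per mouse passed the adjustment under no setting, and without a covariate 4 mice per group allow no permutation p below 0.0286. For libraries apart from the rest, vehicle replicate 1 took 64.9% and 63.5% of the first component when fewer, more variable genes were used.

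The direction relative to other genes turned for lists as follows, with mean log2 differences. With the T cell covariate these were cytokines -0.20, cytotoxic 0.45, exhaustion -0.041, naive -0.19, residency -0.11, cell cycle -0.28, glycolysis -0.21, apoptosis -0.10, heat shock -0.18, melanoma -0.59, macrophage -0.20, dendritic 0.069, neutrophil 0.097, CD4 -0.12 and natural killer 0.12. With the macrophage covariate they were cytotoxic -0.079, cell cycle -0.24, glycolysis -0.23, apoptosis -0.14, melanoma -0.43, dendritic 0.00082, neutrophil 0.17, CD4 -0.29 and natural killer -0.036. Without a filter they were cell cycle -0.10 and melanoma -0.18. Melanoma turned at -0.19 with the block, -0.20 with library weights and -0.41 without both libraries, where cytotoxic genes were at -0.19 and natural killer at -0.25. Fibroblast was at -0.36 with the filter at 5. With each library left out, ribosomal proteins ran from -0.13 to 0.060 and melanoma from -0.35 to -0.10.

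Genes changed sign as follows. Ppp3ca was at 0.028 with classes removed, 0.58 with the macrophage and 0.40 with the T cell covariate, 0.16 and 0.19 under the 2 scalings, 0.076 with library weights, 0.19 without both libraries and -0.24 to 0.14 with each library left out. Fkbp1a was at 0.065 and 0.095 and Nfatc2 at 0.018 and 0.047 under the scalings. Tnf was at 0.27 and 0.14 with the macrophage and T cell covariates, Lyz2 at 0.045 with the macrophage covariate and Gzmb at 1.04 with the T cell covariate.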

Other observations

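The test of gene class, its scalings and the fit with the T cell covariate were chosen after the data were seen.

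The most abundant transcript was annotated to Cmss1, which took 8.01 ± 1.05% of the summed FPKM in the tacrolimus libraries and 8.08 ± 3.00% in the vehicle libraries (SD, n = 4), with 12.3% in vehicle replicate 4. Dct, a melanin synthesis enzyme, had a mean of 16579 FPKM over the 8 libraries. Both were named after their values were seen.

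Genes that are not protein-coding were more frequent among those higher in the tacrolimus libraries. Of 207 annotated genes higher at an unadjusted p under 0.05, 35.3% were pseudogenes, non-coding RNAs or other classes, against 10.6% of the genes tested (Fisher's exact p = 1.37e-21, across genes that are not independent). Among the 2056 lower genes the share was 3.36%. Among the genes higher under median-of-ratios scaling the share was 20.7%, under upper-quartile scaling 24.2% and with each library scaled to the same total 35.5%. Processed pseudogenes were the most frequent of these classes among the genes higher in the values as deposited, with 18 genes.

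T cell effector genes were set against the mean log2 level of Cd3d, Cd3e, Cd3g, Cd8a and Cd8b1, which was 4.15 ± 1.25 with tacrolimus and 6.06 ± 0.89 with vehicle. Lower expression per T cell would leave a lower ratio in the tacrolimus libraries. Of 7 ratios, Pdcd1 differed by -0.47 (exact permutation p = 0.0571, adjusted p = 0.400) and Gzmb by 0.45 (exact permutation p = 0.257, adjusted p = 0.629). The smallest adjusted p was 0.400. The bound set beforehand, that every adjusted p be 0.05 or more, was wrong as an exclusion, since 1 gene alone cannot pass it with 4 mice per group (smallest adjusted p 0.2). With the T cell identity level as a covariate, the cytotoxic list lay higher in the tacrolimus libraries by 0.45. The permutation test over the residual orders did not pass (SE 0.13, p = 0.0132, adjusted p = 0.142 over 25 lists).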
